A study of Mus musculus with 2 samples.

How the data were processed

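Long-read RNA sequencing was done on total RNA of the gastrocnemius, a calf muscle, from female mice aged 36 days, in 2 libraries. The animals were first-generation hybrids of the C57BL/6J and CAST/EiJ strains, so each carried 1 allele of either parent. The labels give replicate 1 and replicate 2 different female numbers and different tissue samples, under 1 shared donor entry, so they were taken as separate animals. They give a start of 2 µg of RNA per library, and 2 added spike-in mixes: the Lexogen isoform and long transcripts, and the Ambion (ERCC) mix 1. Both libraries belong to the same group, so no comparison between conditions could be made.

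The authors deposited, for each library, a table of whole-number read counts per transcript model and a transcript annotation. Per the README beside the files, both were made from filtered alignments to the mm10 mouse genome with the GENCODE M21 annotation. The deposited annotation names TALON gene and transcript numbers for models added from the reads, and the deposited count table gives TALON's classes. Known models matched an annotated transcript. Incomplete splice match (ISM) models held a consecutive part of an annotated chain of introns. NIC models joined annotated splice sites in an unannotated combination, and NNC models used at least 1 unannotated splice site. Genomic models overlapped an annotated gene without fitting its splicing, and antisense and intergenic models formed loci of their own. The aligner, the read correction, the filters and their versions are not given in the sources used here. The count tables list only models with at least 1 read and were not normalized, and replicates were not pooled. The Lexogen transcripts were not analysed here.

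Reads of all models of a gene were summed. Levels in CPM, the usual scaling of counts to library size, were computed on the reads in annotated mouse genes, 797105 in replicate 1 and 1602272 in replicate 2, without spike-ins and without antisense and intergenic loci. One read is worth 1.25 CPM in replicate 1 and 0.624 CPM in replicate 2. A count of 0 allows a level of up to 3.76 CPM and 1.87 CPM (3 counts of the total). Folds against a count of 0 were computed against 3 counts in that library and are given as lower bounds. Intervals of shares are exact Clopper-Pearson 95% intervals, and intervals of folds come from the exact binomial interval of the reads of both libraries. They cover counting error only, since reads without molecular identifiers are not independent molecules.

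Genes were compared between the libraries with Fisher's exact test, two-sided, adjusted by the Benjamini-Hochberg method over the 8096 annotated genes with at least 10 reads summed over both libraries. A call needed an adjusted p under 0.05 and at least a 2-fold difference in CPM. With 1 group there is no residual spread for a count model, so the test compares these 2 libraries and not conditions. TMM factors from edgeR 4.0.16 and size factors from DESeq2 1.42.0 (R 4.3.3) served only as other scalings of the fold. For each gene list the median log2 CPM ratio (pseudocount 1 CPM, members with at least 10 reads summed) was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and also among lists matched on expression in 10 bins and on transcript length in 5 bins. Random members were drawn independently, while genes of a list can shift together between 2 libraries. The random range can therefore be too narrow, and a percentile is a description and not a p-value.

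Transcript models were matched between the libraries by the annotated transcript or by chromosome, strand and intron chain. Single-exon models outside the annotation have no intron chain, so they were pooled per gene and class. The most used transcript was compared for genes with at least 20 reads in each library. Inclusion of an exon was the reads of models that held it between 2 introns, divided by those plus the reads of models with an intron joining its neighbours, for exons with at least 20 such reads in each library. Exons were compared by Fisher's exact test with the same adjustment and a minimum difference of 10 percentage points. For pseudogenes with at least 50 reads, the share of their 25-nt words also found in the transcripts of a protein-coding gene was computed from the M21 transcript sequences.

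Both tests were tested on simulated data that held counting error only, without differences between animals, tissue pieces or transcript lengths. Of 200 genes changed 4-fold among 8057 genes tested, 95% were called in the right direction, with 4 false calls. Of 200 exons shifted by 30 percentage points among 2000 exons, 98% were called, with 3 false calls. These false calls therefore give no error rate for the calls between the 2 libraries. The shares called do not extend to genes and exons with fewer reads than those simulated. Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

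The gene lists, the main tests, the first set of other settings and the rule for named genes were fixed before the data were examined. Chosen after seeing the data were the matching on length, the total without Atp2a1, the gene test without incomplete and Genomic models, the thinning of replicate 2 for the gene test, the search for pseudogene copies, the summaries over variable exons alone, and several tests of explanations. The rule named the 20 genes with the highest mean CPM. It named the 3 members of each list with the highest mean CPM, every myosin heavy chain gene and every sex check gene. It named the 12 most read fixed isoform genes whose most used transcript held under 60% of the reads in both libraries, and the 15 best covered exons of such genes with 10% to 90% inclusion in both. It named the 10 most read genes led by the same NIC or NNC model, the 10 genes with the largest fold in each direction at a mean of at least 20 CPM, and the 5 most read intergenic and antisense loci found in both libraries. The alternatives changed read and gene filters, model classes, pseudocounts, scalings, length definitions and thresholds, or left out each replicate.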

Results

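The data describe the messenger RNA of mouse gastrocnemius, read as long molecules, in 2 libraries from female mice aged 36 days, numbered as separate animals in the labels. The table of replicate 1 held 853589 reads in 58867 transcript models, and that of replicate 2 held 1748822 reads in 97558 models. Annotated mouse genes took 797105 and 1602272 of these reads. The libraries form 1 group, so the values below give the make-up of the tissue pieces read, with the spread between the libraries as the only error. Whether a piece held tissue of a neighbouring muscle was not tested. Reads were found for 12293 annotated genes in replicate 1 and 14383 in replicate 2, and 11352 genes had reads in both. After replicate 2 was thinned at random to the depth of replicate 1, it held 12605 genes, of which 10619 also had reads in replicate 1. Across the 15324 genes with a read in either library, log2(CPM + 1) correlated with Pearson r = 0.907 and Spearman rho = 0.867. Genes are not independent replicates, so no p-value is given.

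Contraction and energy supply dominated the transcriptome. The 20 most abundant genes took 50.1% of the reads in annotated genes in replicate 1 and 38.4% in replicate 2. Ckm, the muscle creatine kinase, was at 72207 ± 15365 CPM (SD, n = 2), Atp2a1, the calcium pump of the fast sarcoplasmic reticulum, at 70087 ± 56450 CPM, and Acta1, skeletal actin, at 68022 ± 10024 CPM. The fast troponin subunits Tnnc2 (44889 ± 4054 CPM) and Tnni2 (6454 ± 459 CPM), the tropomyosin Tpm1 (27836 ± 3286 CPM) and the myosin light chains Mylpf (26826 ± 2482 CPM) and Myl1 (22953 ± 612 CPM) followed. Myh4, the heavy chain of fast glycolytic fibres, was at 14559 ± 5120 CPM, Actn3 at 6707 ± 4549 CPM and Tcap, a Z disc protein, at 7530 ± 3333 CPM. Glycolytic enzymes in this set were Aldoa (15917 ± 3535 CPM), Eno3 (9816 ± 133 CPM), Ldha (7710 ± 368 CPM) and Pgam2 (5668 ± 845 CPM). The mitochondrial carrier Slc25a4 was at 15010 ± 7096 CPM and the ATP synthase subunit Atp5b at 5601 ± 2923 CPM. The calcium-binding proteins Casq1 (5487 ± 1935 CPM), Hrc (4758 ± 2176 CPM) and Pvalb (4754 ± 237 CPM) completed it. The spread was widest for Atp2a1, which alone made up 110003 CPM in replicate 1 and 30171 CPM in replicate 2.

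The myosin heavy chains, which define muscle fibre types, were mostly of the fast glycolytic kind. Myh4 held 93.8% ± 8.06 (SD, n = 2) of the heavy chain reads, with 99.5% of 14562 reads in replicate 1 (95% CI 99.4 to 99.6) and 88.1% of 19891 reads in replicate 2 (87.7 to 88.6). The mean share was 74.6% with known models only and 84.4% without incomplete and Genomic models. These means hide a difference between the libraries. The annotated Myh4-202 had 2018 reads in replicate 1 and 591 in replicate 2, and Myh1-203 had 33 and 318. In replicate 2, 52.5% of Myh4 reads were in a single 3-exon incomplete model, against 6.38% in replicate 1. The share of 88.1% in replicate 2 therefore depends largely on incomplete models. The remainder of the heavy chain reads also differed between the libraries. Myh1, the heavy chain of intermediate fast fibres, held 0.44% in replicate 1 (64 reads) and 6.10% in replicate 2 (1214 reads). Myh2, of fast oxidative fibres, had 0 reads in replicate 1, where 3 counts would be a share of 0.0206% (the exact 95% limit is 0.0253%), and 554 reads or 2.79% in replicate 2. Myh7, of slow fibres, had 0 and 590 reads, the latter 2.97%. Without incomplete and Genomic models Myh7 had 0 and 253 reads. All these shares count every model class, and where the mean Myh4 share was lower the remainder as a whole was larger. The embryonic Myh3 (1 and 2 reads), the neonatal Myh8 (5 and 1 reads) and Myh7b (1 and 3 reads) were near the detection limit in both.

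**Figure D1:**
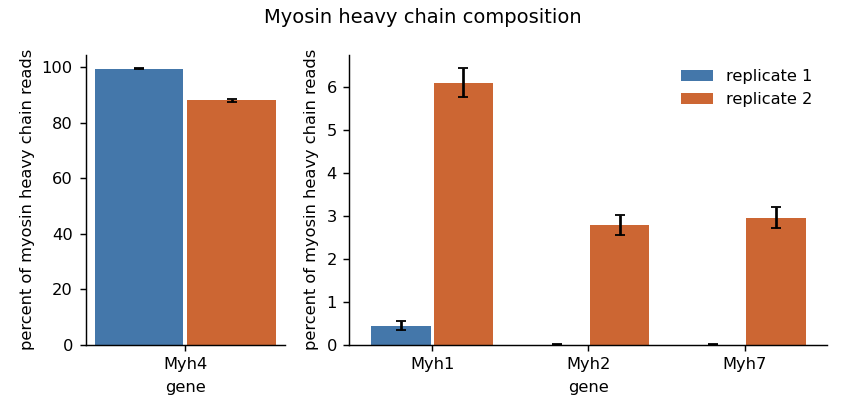
Share of each gene in the reads of all myosin heavy chain genes, all model classes counted (percent, 2 panels with separate scales), in replicate 1 and replicate 2, with exact 95% intervals as error bars. Myh4 held 99.5% and 88.1%, while Myh2 and Myh7 had 0 reads in replicate 1 and 2.79% and 2.97% in replicate 2.

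Slow-fibre genes followed the same split. All 12 members of the slow sarcomere list with enough reads were higher in replicate 2, and the whole list took 0.0388% of the reads in replicate 1 and 1.11% in replicate 2. Tnnt1, slow troponin T, had 7 and 6922 reads, a 492-fold difference (95% CI 239 to 1224), but 94.4% of its reads in replicate 2 were in a single 3-exon incomplete model, and the difference was 63.3-fold (2 and 229 reads) without incomplete and Genomic models. Tnnc1, slow troponin C, had 1 and 2251 reads, a 1120-fold difference (201 to 44251), and Tpm3, slow tropomyosin, had 9 and 2096 reads, a 116-fold difference (60.9 to 254). The main transcript of Tpm3 in replicate 2, Tpm3-205, had 0 and 1906 reads, so the 9 reads of replicate 1 were in other transcripts. Against 3 counts, genes with 0 reads in replicate 1 were at least 249-fold higher for the slow light chain Myl3 (1503 reads in replicate 2), at least 110-fold for Myl2 (663 reads), at least 97.8-fold for Myh7 and at least 79.9-fold for the Z disc protein Myoz2 (482 reads). The lower ends of their exact 95% intervals were 202, 89.2, 79.3 and 64.8. The list's median log2 ratio was 7.49, or 6.47 with genes at 0 set to their bound, and lay at percentile 100 of random lists matched on expression and of those matched on expression and length. Without incomplete and Genomic models all 12 remained higher, and they took 0.0348% of the reads then counted in replicate 1 and 0.726% in replicate 2. Replicate 2 was also 2.05 times deeper and held a smaller share of reads from long transcripts, and the medians of the blood, adipocyte, and Schwann and nerve lists were lower in it (-2.15, -1.50 and -1.67).

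The fast sarcomere list took 24.5% ± 7.09 (SD, n = 2) of all reads, 29.5% in replicate 1 and 19.5% in replicate 2. Most of this gap came from Atp2a1, which made up 110003 of 295486 CPM in replicate 1 and 30171 of 195225 CPM in replicate 2. Of the 16 members of the list, 3 were higher in replicate 2 and 3 lower. Myh1 (9.44-fold), Myh2 (at least 91.9-fold against 3 counts, lower end of the exact 95% interval 74.5) and the tropomyosin Tpm2 (2.54-fold) were higher, and Atp2a1 (3.65-fold), Mybpc2 (3.06-fold) and Actn3 (2.84-fold) were lower. Tnnc2, Tpm1, Mylpf and Myl1 differed by less than 1.2-fold. The median log2 ratio of the list was -0.13, at percentile 0.38 of matched random lists. The middle 95% of these lists ran from 0.03 to 0.88.

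Mitochondrial genes were higher in replicate 2. All 22 members of the list of nuclear encoded respiration genes had a ratio above 1, and 11 passed the test (percentile 99.97). Slc25a4 was 2.00-fold, Atp5b 2.17-fold and the cytochrome oxidase subunit Cox4i1 2.33-fold higher. With Atp2a1 left out of the total 6 passed, as the folds of Slc25a4 (1.84), Atp5b (1.99), Cox6c (1.85), Cycs (1.92) and Ndufb9 (1.89) then lay just under the threshold. Of the 13 tested genes of the mitochondrial genome 11 were higher, such as mt-Cytb (3.47-fold), mt-Co1 (3.09-fold) and mt-Nd1 (2.56-fold), and none was lower. The list took 0.313% and 1.00% of the reads, and annotated pseudogene copies of some of these genes share their sequence, which leaves single levels uncertain. Of 15 tested genes of fatty acid use 5 were higher and none lower, led by the fatty acid carrier Fabp3 at 10.6-fold (178 and 3782 reads), while Pdk4 (1.19-fold) and Hadhb (1.65-fold) did not pass. Its median lay inside the random range, at percentile 65.8. Glycogen and glycolysis genes took 5.79% and 4.81% of the reads. Gapdh entered this sum at 71.5 and 76.1 CPM, while 8 pseudogene copies of Gapdh outside the list held 5689 and 2976 CPM. Of 19 members, 2 were lower in replicate 2, the glycogen phosphorylase Pygm (2.14-fold) and its kinase subunit Phka1 (2.56-fold), and the median log2 ratio of -0.44 lay at percentile 0. Aldoa was 1.37-fold lower, below the fold threshold, and Eno3 and Ldha differed by less than 1.1-fold.

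Of 17 filament and Z disc genes 2 were higher in replicate 2 and none lower (percentile 20.9), with Acta1 at 0.811 times, Tcap at 1.91 times and Des, the muscle intermediate filament, at 1.35 times the level of replicate 1. Of 17 genes of calcium release and excitation 1 was higher and 1 lower. The lower one was Srl, a protein of the sarcoplasmic reticulum, at 2.12-fold. Hrc was 1.956-fold and Trdn 1.86-fold higher without passing, and Hrc passed under TMM scaling. The median of this list lay at percentile 0.89, and at 8.54 when length was matched too. Of 13 tested muscle regulators 2, Mef2a and Sox6, were lower in replicate 2 (percentile 10.8), and the highest were Tbx15 (148 ± 35.9 CPM, SD, n = 2), Nfix (132 ± 8.43 CPM) and Mef2c (125 ± 31.4 CPM). Of 14 atrophy and growth genes 2 were lower (percentile 0.31). The ubiquitin ligase Trim63 was 2.30-fold lower, while Trim54 (305 ± 62.1 CPM) and the metallothionein Mt1 (97.3 ± 2.75 CPM) did not pass. The embryonic and neonatal list had 5 tested genes, of which the fetal actin Actc1 was 2.44-fold lower and 1 other gene, Myl4, 2.65-fold higher (percentile 25.04). H19 stayed at 401 ± 32.4 CPM and Chrna1 at 24.1 ± 4.95 CPM. At the neuromuscular junction 1 of 9 genes, the acetylcholinesterase Ache, was lower (3.52-fold), Rapsn was at 37.9 ± 6.77 CPM and the list at percentile 18.2.

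Markers of other cell types were scarce and some moved between the libraries. Blood genes took 0.257% of the reads in replicate 1 and 0.0567% in replicate 2, and 4 of 6 tested genes were lower in replicate 2. These were the globins Hba-a1 (4.34-fold), Hba-a2 (4.59-fold), Hbb-bs (4.94-fold) and Hbb-bt (7.00-fold), near-identical pairs whose reads can be split. Of 8 adipocyte genes 3 were lower (percentile 0), among them Cfd at 5.86-fold, while Car3, which muscle also expresses, was 1.43-fold higher and Fabp4 1.24-fold higher, both without passing. Of 4 tested Schwann and nerve genes 2 were lower (percentile 0.03), including the myelin gene Mbp at 5.73-fold. Pmp22, at 1.72-fold lower, missed the fold threshold. Of 14 fibroblast and matrix genes 2 were lower and 1 higher (percentile 12.1), with Gsn 3.06-fold and Col3a1 2.10-fold lower and Sparc at 383.8 ± 30.04 CPM (SD, n = 2). Tendon genes had 2 of 8 higher (percentile 95.8), of which Chad was lost with Atp2a1 left out of the total, with the tendon regulator Scx at 3.48-fold and Thbs4 and Fmod at 48.5 ± 8.23 CPM and 45.7 ± 9.90 CPM. None of 9 endothelial genes passed (percentile 29.9; Egfl7 42.8 ± 7.37 CPM, Cldn5 35.4 ± 3.22 CPM). Of 9 pericyte and smooth muscle genes 1 was lower (percentile 35.3), and Rgs5 (84.8 ± 2.51 CPM), Abcc9 (21.6 ± 10.3 CPM) and Acta2 (20.96 ± 2.29 CPM) did not pass. Of 5 satellite cell genes 1, Itga7, was lower at 2.397-fold, and Cdh15 was at 17.8 ± 6.70 CPM (percentile 65.0). Des, also in the filament and Z disc list, held 2803 of the 2888 CPM of this list in replicate 1. In replicate 2 it held 3789 of 3864 CPM, so the list does not measure satellite cells alone. Of 6 tested immune genes 1, C1qc with 2 and 22 reads, was higher (5.47-fold, 95% CI 1.35 to 48.0), a call lost in several of the alternatives, and Lyz2 and Cd74 were at 19.4 ± 4.36 CPM and 18.5 ± 1.26 CPM (percentile 84.8).

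Xist and the Y-linked genes fitted the female label: Xist had 4 and 26 reads, and Ddx3y, Eif2s3y, Kdm5d and Uty had 0 reads in both libraries. Tsix, the antisense partner of Xist, had more reads than Xist, 9 and 55 (3.04-fold higher in replicate 2), and the cause was not tested. Of 9 stress and early response genes 1, the small heat shock protein Cryab, was higher in replicate 2 at 2.56-fold (percentile 39.7), and Hspb1 and Nr4a1 were at 200.5 ± 13.9 CPM and 71.3 ± 2.02 CPM (SD, n = 2). None of 11 clock genes passed (percentile 43.4), although Tef and Nr1d2 were lower with Atp2a1 left out of the total, with Tef at 100.5 ± 42.4 CPM, Dbp at 96.0 ± 16.9 CPM and Nr1d1 at 60.4 ± 10.4 CPM. Adjusted over the list alone, 3 genes passed in the glycolysis list, 13 in the mitochondrial genome list, 5 in each of the blood, adipocyte and fibroblast lists, and 2 in each of the satellite cell and sex check lists, and the other lists kept the counts given. With Atp2a1 left out of the total, genes that also became calls, all lower in replicate 2, included Pkm, Mef2d, Fn1 and Retn.

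**Figure D2:**
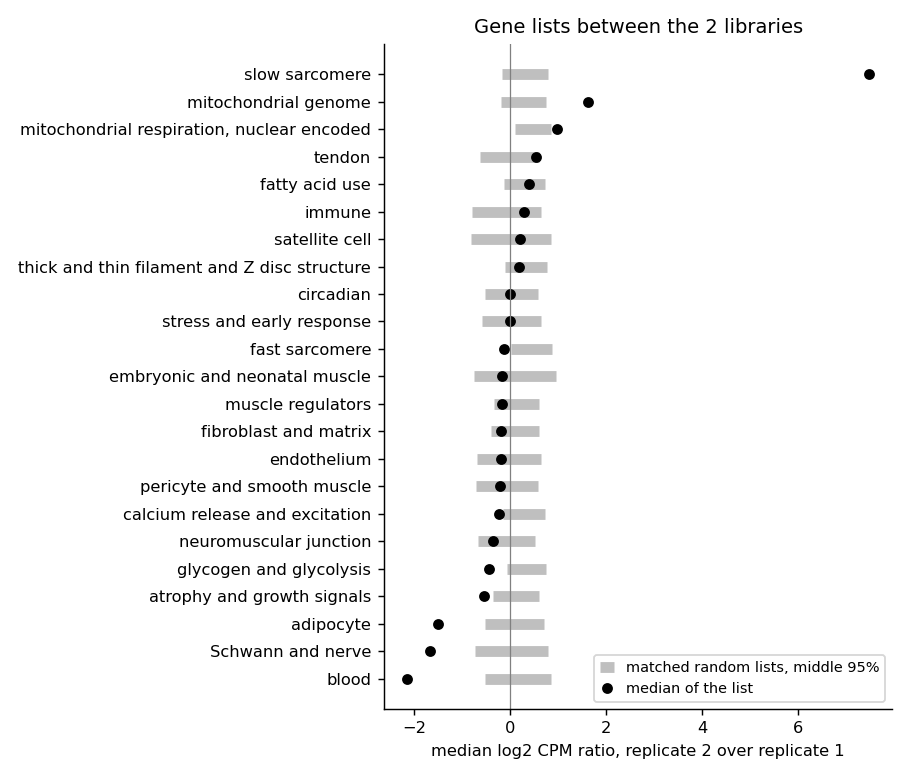
Median log2 CPM ratio of each gene list, replicate 2 over replicate 1 (points), and the middle 95% of random lists of the same size matched on expression (grey bars). The slow sarcomere list lies farthest to the right at 7.49 and the blood list farthest to the left at -2.15.

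Over all genes, 911 of 8096 tested by Fisher's exact test differed between the libraries, 468 higher and 443 lower in replicate 2. The split depended on the total and on the models counted. With Atp2a1 left out of the total, 348 genes were higher and 567 lower, since the median log2 ratio of all genes moved from 0.06 to -0.07. With known models only, 255 were higher and 587 lower. The 10 largest differences upward among genes of at least 20 CPM were 8 members of the slow and fast lists named above, the heart-type lactate dehydrogenase Ldhb (3 and 651 reads, 108-fold, 95% CI 36.8 to 525) and the stretch-responsive Ankrd2 (2 and 430 reads, 107-fold, 29.4 to 886). Of the 10 largest differences downward, the first was Podn, a matrix protein (41 and 3 reads, 27.5-fold, 8.76 to 139). Apart from processed copies, the next was the fat droplet gene Cidec (55 and 11 reads, 10.1-fold). Rnf170 (8.50-fold), Lingo3 (7.44-fold), Ifi27l2a (7.41-fold) and Hbb-bt were also among the 10, and the call of Rnf170 was lost with known models only. The other 4 were the processed copies Gm6055 (17.1-fold), Oaz1-ps (16.1-fold), Pgk1-rs7 (12.7-fold) and Apoo-ps (6.53-fold), whose reads can come from near-identical parent genes.

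Most reads matched annotated transcripts. Known models held 63.9% ± 1.01 (SD, n = 2) of the mouse reads, and incomplete splice matches held 10.4% in replicate 1 and 14.8% in replicate 2. NNC models, which use an unannotated splice site, held 12.9% and 4.59%, and NIC models 4.59% and 3.47%. Genomic models held 4.52% and 7.59%, antisense loci 2.46% and 5.33%, and intergenic loci 0.498% and 1.05%, and over 94% of the reads of these 3 classes were in single-exon models. The fall of the NNC share between the libraries came mostly from a single model of Atp2a1, which held 77.3% and 54.2% of all NNC reads. Without it the shares were 2.94% and 2.10%.

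**Figure D3:**
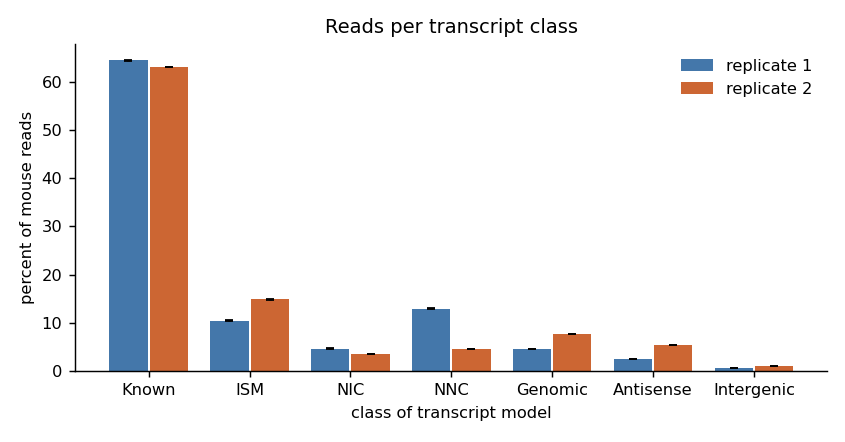
Share of mouse reads (percent, bars) in each class of transcript model in replicate 1 and replicate 2, with exact 95% intervals that are narrower than the line width for most bars. Known models held 64.6% and 63.1%, and the NNC class 12.9% and 4.59%.

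Transcript choice was mostly shared by the libraries. Of 3204 genes with at least 20 reads in each, 2745 (85.7%) had the same most used transcript, which held a median 77.1% of the gene's reads in replicate 1 and 73.0% in replicate 2. Of the 459 genes that differed, 299 were led by an incomplete or Genomic model in replicate 2 alone and 10 in replicate 1 alone. Without these classes 2416 of 2518 genes (95.9%) shared the leading transcript. Of the 100 muscle isoform genes fixed for inspection, 65 had at least 50 reads in each library, 51 of them shared the leading transcript, and in 29 it held under 60% of reads in both. Some of the 51, such as Neb and Ldb3, were led in both libraries by pooled single-exon models, which need not be the same transcript. Without incomplete and Genomic models 44 of 49 genes shared the leading transcript. Some genes were nearly uniform: Tpm1-205 held 94.9% ± 0.797 (SD, n = 2) of Tpm1 reads, Acta1-201 91.0% ± 1.28 and Ckm-203 90.5% ± 1.64. Among the 12 named for diversity, Eno3 used Eno3-201 at 52.5% ± 0.198 and Eno3-202 at 23.8% ± 2.13, Tmod4 used Tmod4-201 at 39.6% ± 1.25 and Tmod4-202 at 29.0% ± 1.09, and Asph used Asph-206 at 53.1% ± 7.03. Bin1 was led by an unannotated chain of 14 exons at 52.9% ± 4.68. The leading model of Ryr1, the calcium release channel, was an incomplete match of 16 exons (29.9% ± 9.34). For Myh4 the leading model was an unannotated chain of 40 exons in replicate 1 (24.8%) and a 3-exon incomplete match in replicate 2, at 52.5% against 6.38% in replicate 1. Pygm-201 held 55.5% and 37.4% of Pygm reads and Myh1-203 51.6% and 26.2% of Myh1 reads. Mybpc1 was led by Mybpc1-202 in replicate 1 (46.7%) and by an unannotated chain of 31 exons in replicate 2 (23.6%). In replicate 2 that chain, with 163 reads, was nearly level with Mybpc1-202, with 160 reads (23.2%). Tnnt3 and Ttn were led in replicate 2 by their pooled single-exon models, at 16.8% and 59.6%. Pde4dip was led by its pool in both libraries, at 9.12% and 34.5%.

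Of 3235 exons in 1420 genes, 323 were included in 10% to 90% of reads in both libraries. Over these 323 exons inclusion correlated with Pearson r = 0.916 and Spearman rho = 0.886, with a median difference of 5.78 percentage points, and exons of a gene are not independent replicates. Myl1 used a pair of short exons: its 28-nt exon at chromosome 1, 66934246 to 66934273 (mm10), was included in 22.7% and 21.8% of reads, and its 25-nt exon at 66934518 to 66934542 in 79.9% and 81.3%. Bin1 included its 72-nt exon (chromosome 18, 32431671 to 32431742) in 31.2% and 30.3%, Myl6 its 45-nt exon (chromosome 10, 128491720 to 128491764) in 47.3% and 47.8%, and Smyd1 its 39-nt exon (chromosome 6, 71235343 to 71235381) in 39.5% and 44.1%. Values for the 20-nt exon of Myl6 were 20.6% and 21.3%, for the 84-nt and 72-nt exons of Ktn1 12.1% and 12.7% and 61.3% and 64.1%, for the 153-nt exon of Pde4dip 81.5% and 77.9%, for the 303-nt exon of Ttn 35.8% and 54.3%, and for the unannotated 180-nt exon of Asph 31.0% and 17.8%. None of these passed the test.

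By Fisher's exact test 12 exons differed, 9 of them in the fixed isoform genes and 8 of them among the 323 variable exons. Of those 323 exons, 100 differed by at least 10 percentage points, so most such differences did not pass at the reads available. Tnnt3, fast troponin T, exchanged a pair of 41-nt exons. The exon at chromosome 7, 142513665 to 142513705, fell from 86.5% of 2386 reads in replicate 1 to 56.8% of 5372 reads in replicate 2 (adjusted p = 3.21e-154, Fisher's exact test), and the exon at 142514326 to 142514366 went from 13.3% to 42.6% (adjusted p = 1.69e-156, Fisher's exact test). Mybpc1, the slow myosin-binding protein C, included its 42-nt exon (chromosome 10, 88582007 to 88582048) in 56.1% and 87.9%. Neb, the thin filament ruler nebulin, included its 93-nt exon (chromosome 2, 52150537 to 52150629) in 13.3% of 75 reads and 47.7% of 128 reads.

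Unannotated splice chains with several reads mostly recurred in the other library. Of NIC models with at least 5 reads in one library, 93.4% ± 5.69 (SD, n = 2) were found in the other, and of NNC models 91.3% ± 8.86, against 98.3% ± 1.68 of known models. When a single read sufficed, the shares of NIC and NNC models were 36.6% and 23.0%. Recurrence does not show that a chain is real, since an alignment error shared by both libraries would recur too. In 94 genes the same NIC or NNC chain led in both libraries. The 10 most read were Atp2a1 (90.9% ± 3.92 of the gene's reads), Aldoa (80.4% ± 6.14), Tnni2 (63.6% ± 9.27), Oaz1 (95.1% ± 0.443), Srl (47.5% ± 9.88), the mitochondrial channel Vdac3 (82.2% ± 6.47), Idh3b (78.7% ± 1.21), Bin1, Hfe2 (35.3% ± 5.94) and Mrpl33 (96.4% ± 0.256). The Bin1 chain was classed NIC in replicate 1 and NNC in replicate 2. The Atp2a1 model, at chromosome 7, 126445858 to 126463108 (mm10, minus strand), had 22 exons and 82108 and 42587 reads. Compared with the annotated Atp2a1-201 of 23 exons, which had 0 reads in both, it lacked the coding 18-nt exon at 126462500 to 126462517. Its first exon ran 26 nt farther, to 126462779 in place of 126462805. The net gain of 8 nt is not a multiple of 3. No read held the short exon between 2 introns. It was the end exon of models with 12 reads in replicate 1 and 6 in replicate 2, which is 0.0142% of 84362 and 0.0136% of 44267 reads that ended in it or skipped it.

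**Figure D4:**
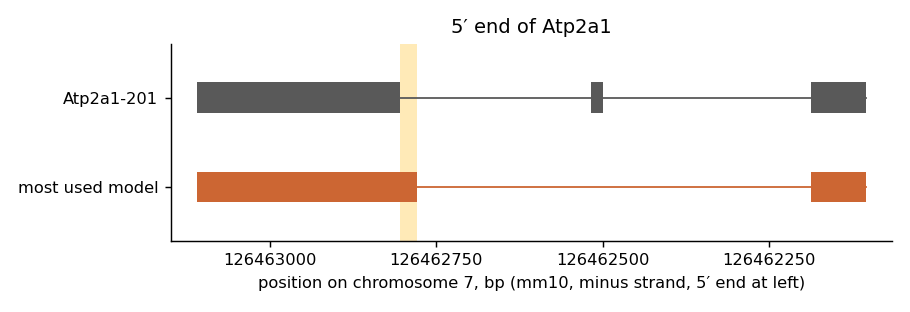
The 5′ end of Atp2a1 on chromosome 7 (mm10 position in bp, minus strand, 5′ end at left), with boxes for exons and lines for introns. The annotated Atp2a1-201 (top) holds the 18-nt exon at 126462500 to 126462517, while the most used model (bottom) lacks it and has a first exon longer by 26 nt (shaded).

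Of the loci outside annotated genes, 4570 antisense and 952 intergenic ones overlapped on the same strand in both libraries, and the 5 most read of each class were single-exon. An antisense locus over Klhl31 (chromosome 9, 77656520 to 77658193, minus strand) had 2672 and 8737 reads, against 93 and 124 reads of Klhl31 itself. Antisense loci over Ptp4a2 (chromosome 4, 129839151 to 129839678) had 301 and 1588 reads, over Cdv3 (chromosome 9, 103354312 to 103355313) 247 and 1514 reads, over Msrb3 (chromosome 10, 120781096 to 120783314) 176 and 1072 reads, and over 2900097C17Rik (chromosome 2, 156388065 to 156391514) 178 and 902 reads. The intergenic loci lay at the end of Gm12033 on chromosome 11 (20334833 to 20335012; 152 and 1513 reads), on chromosome 15 with no annotated gene with reads within 86580 bp (103619061 to 103619240; 147 and 839 reads), at the end of Dyrk1b and on its opposite strand on chromosome 7 (28187294 to 28189355; 208 and 375 reads), at the end of Pgk1-rs7 on chromosome 12 (10898566 to 10898986; 121 and 150 reads) and at the end of Gm5537 on chromosome 3 (58102571 to 58102996; 84 and 127 reads). Those beside a gene shared only 1 end position with it. Of these neighbours, Gm12033 shares 97.4% of its 25-nt words with Gapdh, and Pgk1-rs7 and Gm5537 share 100% with Pgk1. Reads at these loci can therefore come from Gapdh or Pgk1.

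Transcript length separated the libraries. The median log2 CPM ratio of replicate 2 over replicate 1 was 0.62 for genes whose longest annotated transcript is under 1 kb, 0.41 from 1 to 2 kb, -0.05 from 2 to 4 kb and -0.27 at 4 kb and more. Genes under 1 kb took 16.7% of the reads in replicate 1 and 22.8% in replicate 2. Incomplete splice matches held 6.14% and 10.05% of the reads of genes under 1 kb, and 25.6% and 28.5% at 4 kb and more. Suffix models, which hold the 3′ part of a transcript, made up 75.7% and 65.9% of incomplete match reads, and prefix models 3.60% and 2.26%. ERCC spike-ins had 31436 reads in replicate 1 and 34060 in replicate 2, a ratio of 1.08, while mouse reads had a ratio of 2.09. The 30 spike-ins with at least 10 reads in each library correlated with Pearson r = 0.996 and Spearman rho = 0.989 across spike-ins.

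**Figure D5:**
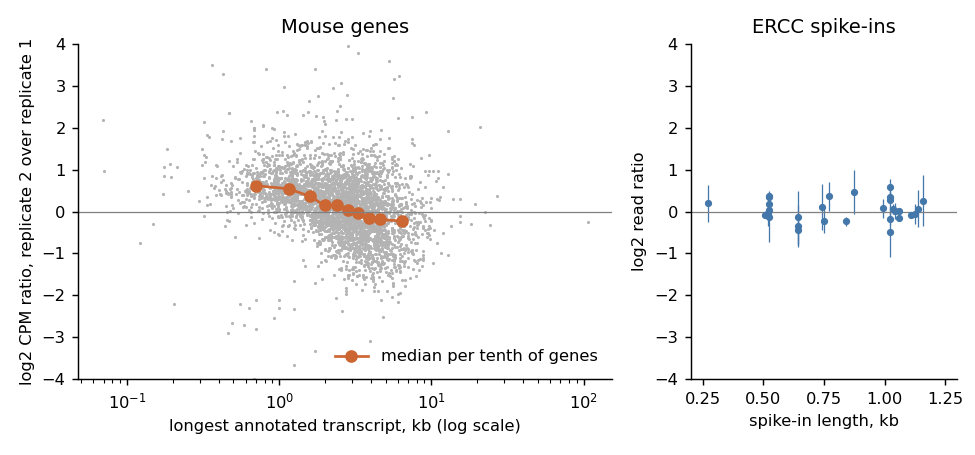
Left, log2 CPM ratio of replicate 2 over replicate 1 against the longest annotated transcript (kb, log scale) for mouse genes with at least 50 reads summed (grey points, those beyond ±4 not shown) and the median of genes binned by length (orange). Right, log2 ratio of ERCC reads against spike-in length for the 30 spike-ins with at least 10 reads in each library, with 1 standard error from the counts; the median of the plotted mouse genes falls from 0.62 under 1 kb to -0.19 at 4 kb and more.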

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

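The tests of depth, of the spike-in slope and of the CAST allele, and the matching of lists on length, were chosen after seeing the data. The design names no biological difference between the 2 libraries, so no biological factor was tested.

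Signal lay in data outside the main comparisons, above the limit that a count of 0 allows. ERCC spike-ins had 31436 reads in replicate 1 and 34060 in replicate 2. Reads antisense to ERCC sequences numbered 204 and 199, or 0.645% and 0.581% of ERCC reads, but 165 and 163 of them were on 1 spike-in with 0 sense reads, and without it the shares were 0.124% and 0.106%. Antisense loci of the mouse genome held 20661 and 93883 reads, 2.53% and 5.54% of the reads in antisense loci and annotated genes, and intergenic loci held 4183 and 18408 reads.

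Many genes of the slow sarcomere list, and Myh2, were near 0 reads in replicate 1 and abundant in replicate 2. Lower depth of replicate 1 is argued against: at the CPM of replicate 2, replicate 1 would hold a median of 311.7 reads per slow sarcomere gene, and it held 2.5. Loss of long molecules from replicate 2 is also argued against, since the list lay at percentile 100 of lists matched on expression and length, and heart muscle carried into replicate 2 is argued against by 1 Myh6 read, 0.169% of the 590 Myh7 reads, with 1 read of Tnni3 and 0 of Nppa. A larger share of slow and oxidative fibres in the piece of muscle used for replicate 2 may explain the pattern, and it stays open: the respiration list lay at percentile 100 when length was matched too, but the fatty acid list reached only 88.3, and the blood, adipocyte, and Schwann and nerve lists moved too (-2.15, -1.50 and -1.67). The animal, the dissected piece and tissue of a neighbouring muscle such as the soleus cannot be told apart with 1 library each.

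Longer transcripts held a smaller share of reads in replicate 2. The fibre type difference stays open as a cause: the rank correlation of ratio with length over 3661 genes was -0.39, and -0.40 without the genes of the fixed lists (101.2% of its size), but 3474 genes remained, and removing so few could hardly have changed it. Loss of long molecules after the spike-ins were added could not be decided: the ERCC log2 ratio changed by -0.33 per doubling of length (95% bootstrap interval -0.45 to 0.00, 29 spike-ins), and mouse genes of the same lengths by 0.04 (-0.28 to 0.35). More broken or incomplete molecules in replicate 2 could not be decided either. The gap in incomplete matches between the libraries was 1.08 points narrower at 4 kb and more than under 1 kb (a difference of -1.08, 95% interval -1.47 to -0.68), but 1.92 points wider when genes were classed by their most used known transcript.

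Nearly all Atp2a1 reads sat in a model that lacks an annotated 18-nt exon. A splice variant of the CAST allele alone could not be decided. If aligned correctly, a B6 allele spliced as annotated would give about as many reads with the exon as without. Instead 0 reads held it between 2 introns and 0.0140% of 128629 reads ended in it. Were the exon missed in alignment, reads of the B6 allele would lack it too, so these counts cannot tell. The exon may have been missed in alignment, although most short exons were seldom skipped through unannotated junctions. Over 131 other annotated internal exons of 25 nt or less, reads skipped the exon this way in a median of 1.08% and a mean of 22.7% of spanning reads, with 34 of them over 10%. For 12522 exons of 60 to 150 nt the median was 0% and the mean 0.209% (difference of means 16.2 to 29.3 points, 95% bootstrap interval). Exons missed through annotated junctions were not counted, and each exon weighed the same whatever its reads. The 7-nt exon of Tnni2 and the 19-nt exon of Mrpl33, in genes also led by unannotated models, were skipped this way in 100% and 99.1% of reads, and no genome sequence was used here to look at the splice sites.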

How the results depend on the processing

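Of 23 gene lists, 10 lay outside the random range in the main setting, with either other pseudocount and with TMM scaling, and 9 did when length was matched too. Matching on length, leaving Atp2a1 out of the total and leaving out incomplete and Genomic models in the gene test (1022 called genes) were chosen after seeing the data, as was thinning replicate 2, which left 709 called genes of which 620 were also called at full depth. The count of called genes was 911 and became 1437 at a fold of 1.5 and 226 at a fold of 4. Detection in both libraries fell from 11352 genes to 6877 with at least 5 reads and 4971 with at least 10, and the gene correlation fell to 0.785 with a pseudocount of 0.1, each by construction of the threshold or scale. The share of reads in known models rose to 67.8% among models with at least 5 reads and 67.1% in annotated genes. The Myh4 share of 93.8% became 74.6% with known models only and 84.4% without incomplete and Genomic models, and without one of the replicates it ran from 88.1% to 99.5%. Both settings without incomplete models drop 9201 Myh4 reads of replicate 2 that were in 1 such model. Why that model held so many reads was not tested. The median share of the leading transcript, 75.1%, was 92.4% without incomplete and Genomic models, 99.6% with known models only, 71.2% with at least 10 reads and 82.0% with at least 100, where 688 genes shared it because fewer were tested. With known models only, 90 exons lay between 10% and 90% inclusion and 4 differed, since 378 exons were then tested. Of NIC and NNC models, 36.6% and 23.0% recurred when a single read sufficed in one library, and 63.5% and 61.4% when 5 reads were asked of both. The incomplete share at 4 kb and more was 30.3% by the most used known transcript. Of 913 recomputed ratios of 94 named genes, 874 kept their side of the threshold, 14 lost a call, 24 gained one and 1 reversed: Thbs4, at -1.42 with known models only; the cause was not tested. Leaving out a replicate leaves 1 library, a value with no spread. Depth limits genes with few reads: a count of 0 allows 3.76 CPM in replicate 1 and 1.87 CPM in replicate 2.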

Other observations

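Genes of oxidative muscle outside the fixed lists, picked after their values were seen, went the same way as the slow sarcomere list. Mb, the oxygen store myoglobin, had 24 and 2089 reads, and Csrp3, a Z disc protein of slow and heart muscle, had 0 and 360 reads. Of 12 heart muscle genes listed for the contamination test, Actc1 had 558 and 459 reads, Myl4 9 and 48, Sbk2 6 and 42, and Tnnt2 1 and 2.

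Reads that match Gapdh lay mostly on its processed copies. Gapdh itself was at 73.8 ± 3.28 CPM (SD, n = 2), far below its neighbours in glycolysis, while 8 annotated pseudogenes that share at least 50% of their 25-nt words with Gapdh transcripts held 5689 CPM in replicate 1 and 2976 CPM in replicate 2. Gm12671, all of whose words occur in Gapdh transcripts, was at 2140 and 497 CPM, Gm12033 at 1336 and 269 CPM, Gm5559 at 1085 and 986 CPM and Gm7336 at 931 and 1020 CPM. Rpl21 showed the same, at 32.5 CPM against 359 CPM over 3 copies, as did Rpl35a, at 44.1 CPM against 282 CPM over 3 copies. Of 97 pseudogenes with at least 50 reads, 94 shared at least 50% of their words with a protein-coding gene, and 19 of these were above it in mean CPM. Gene levels of families with such copies are therefore uncertain in these tables.

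Tnnt1 reads of replicate 2 were concentrated in a single incomplete match of 3 exons, which held 94.4% of its 6922 reads, while 12 reads followed an unannotated chain of 12 exons.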
